A study of Mus musculus with 17 samples.

How the data were processed

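Gene expression was measured in whole blood of 17 female C57BL/6JJcl mice aged 8 weeks, an inbred laboratory strain, killed 24 h after total-body exposure to X-rays. Per the labels, 5 mice received 0 Gy and served as controls, and 4 mice each received 0.5, 1.0 or 3.0 Gy. Blood went immediately into an RNA-stabilising tube, and per the labels' protocols 200 ng of purified total RNA was turned into biotin-labelled complementary RNA and hybridised to 1 Affymetrix mouse genome array per mouse. On this platform a transcript is read by a set of short probes, and the summary of such a probe set is the measured value. The labels call the samples biological replicates.

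The authors deposited log2 values for 45101 probe sets, and the submitters' processing notes name RMA (robust multi-array average, which corrects background, makes the intensity distributions of all arrays alike and summarises the probes of a set) together with R version 3.3.2. The RMA software, its settings, the probe-to-gene definition and any filter are not given in the sources used here. RMA makes the probe intensities of the arrays alike in distribution, so a change of most genes in the same direction would be partly removed from these values, and a fall of many abundant transcripts can appear as a rise of others. The deposited values still differed somewhat, with 75th percentiles from 4.77 to 4.95 over the arrays. RMA also pulls dim probe sets towards background, so fold changes of weakly expressed genes are understated. No scan date or other batch was used here, and signal over background cannot be read from the deposited values. For arrays, the number of mice per group limits the precision.

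Gene names came from a table of platform annotation, in which 34945 probe sets carried 1 gene symbol, 932 carried several, 9160 were unnamed and 64 were control probe sets, left out of the genes. Updating symbols through gene numbers of a current mouse gene table changed 0 of them. Probe sets with several symbols were not named. For each of the 18193 genes the probe set with the highest mean over the 17 arrays was used, and a gene was kept when that probe set lay above its array's own 50th percentile in at least 4 arrays, which left 12696 genes. Of these, 7482 had more than 1 probe set, and 1210 were represented by a probe set of the _x_at or _s_at type, which can bind several related transcripts.

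The deposited log2 values were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 4 group means fitted over all 17 arrays, so that the groups shared an estimate of the spread. Contrasts compared each dose with control and the doses with each other, a second model fitted a slope on the dose in Gy, and an F test asked for a change at any dose. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 12696 genes, and an adjusted p under 0.05 was the threshold for a call. Fold changes are differences of group means on the log2 scale, with limma's moderated standard errors.

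Before the data were examined, 20 gene lists were written from general knowledge: p53 target genes, B cells, T cells, NK and cytotoxic cells, mature neutrophils, immature granulocytes, monocytes, dendritic cells, platelets and megakaryocytes, red cells and reticulocytes, cell division, DNA replication, DNA repair, interferon-response genes, NF-kB and inflammatory genes, MHC class II and antigen presentation, ribosomal proteins, oxidative phosphorylation, oxidative-stress response (NRF2) and apoptosis regulators. Each was tested against all other genes with camera from limma at its preset correlation of 0.01 between genes, and again with a correlation estimated for each list and with fry, which asks whether the genes of a list move, on balance, in one direction. The mean level of each list per array was compared between a dose and control with a two-sided exact permutation test over 126 regroupings, whose smallest p is 0.00794, and adjusted over 60 comparisons.

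The genes named in the text followed a rule fixed at the same time: per dose the 8 largest rises and 8 largest falls among called genes whose dose arrays all lay outside the range of the 5 control arrays, up to 4 members of each list with the smallest p at 3.0 Gy (8 for p53 target genes, B cells and T cells), and the 5 genes with the smallest p in each direction for the trend and for the differences between 1.0 and 0.5 Gy and between 3.0 and 1.0 Gy. Members of lists in which 5 or fewer genes were called in a direction, genes called in opposite directions at different doses, genes ordered by dose and genes specific to the lower doses were named outside this rule, after their values were seen. Probe sets of the _x_at and _s_at types and of the immunoglobulin, globin and Slfn families can bind several members. Those printed here are Rps18, Sesn1, H2-Aa, H2-Ab1, Clec4d, Hdc, Slc4a1, Itgb5, Mcm5, Adpgk, S100a8, Cdca8, Ms4a6d, Tcf4, Tor3a, Ifi27l2b, Ighv14-2 and Slfn4.

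Replicate arrays were compared first: 0 pairs of columns were identical, and the closest pair within a group differed by 0.212 log2 units (root mean square). Alternatives fixed before the data were examined changed the choice of probe set, the filter, the normalization, the spread model, array weights, the arrays in the fit, the fold threshold, the dose scale and the set test, left out each array in turn, or added the replicate number as a block. A fit with the 18S ribosomal RNA level of each array as a covariate was added after the data were seen. Comparisons against the same controls were set beside 100 simulations of unchanged groups and beside 10 splits of the controls. The analysis was tested on simulated data with 200 genes changed among the 12696. Recovery at a log2 change of 0.5 was 42% for 0.5 Gy, 50% for 1.0 Gy and 34% for 3.0 Gy. At a log2 change of 1 it was 94%, 90% and 92%, and 8, 9 and 5 of the 12496 unchanged genes were called. The simulated values were drawn independently for each gene, so these figures do not cover genes that move together in an array. Figures were drawn with matplotlib.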

Results

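Whole blood of 17 mice was profiled 24 h after total-body exposure to X-rays, to find how gene expression in blood depends on the dose. The groups were 5 unirradiated controls and 4 mice each at 0.5, 1.0 and 3.0 Gy, with 1 array per mouse. Values are log2 RMA levels as the authors deposited them, and errors of group means are SDs (n = 5 for control and n = 4 for each dose). Array medians lay between 3.47 and 3.57, and each 3.0 Gy median lay above every control (difference of means 0.046, exact permutation p = 0.0317). Across all probe sets, which are not independent replicates, pairs of arrays within a group correlated with a median r of 0.987 and pairs between groups with a median r of 0.971. After the filter 12696 genes were tested.

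Control probe sets for 18S ribosomal RNA, the RNA of the small ribosomal subunit, separated the groups in a different order from the dose. Their mean level was 10.52 ± 0.49 in controls, 12.69 ± 0.77 at 0.5 Gy, 13.28 ± 0.28 at 1.0 Gy and 10.68 ± 0.14 at 3.0 Gy. The differences from control were 2.17 and 2.76 log2 units at the lower doses (exact permutation p = 0.00794 for each, the smallest that these group sizes can give) and 0.16 at 3.0 Gy (exact permutation p = 0.587). The labels name no batch that could be set beside this split. Of 12 comparisons of 4 array measures with control, 4 had an exact permutation p under 0.05. The one not named so far was the difference between the 3' and 5' control probe sets of Actb, 0.027 at 0.5 Gy against 0.132 in controls (difference -0.105, exact permutation p = 0.0159).

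**Figure D1:**
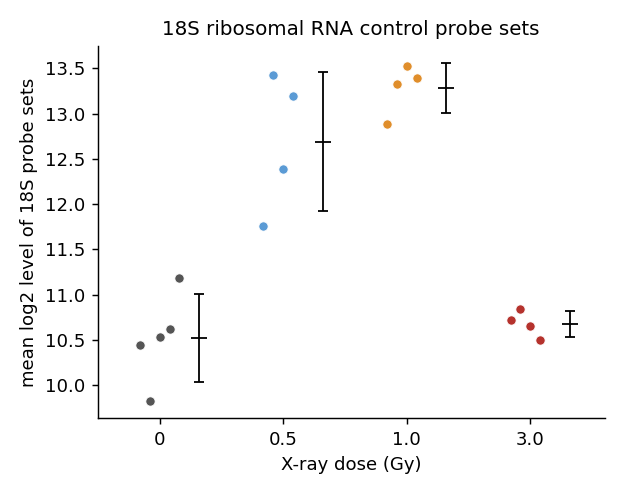
Mean log2 level of the 18S ribosomal RNA control probe sets (vertical axis) in each of the 17 arrays, by X-ray dose in Gy (horizontal axis, groups evenly spaced). Points are single mice and bars show the group mean and SD; all arrays at 0.5 and 1.0 Gy lie at 11.76 or above, and all control and 3.0 Gy arrays lie at 11.18 or below.

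The first comparison asked what 0.5 Gy changed against control. Every gene of the list for platelets, the cell fragments that start clotting, was higher, and 30 of 40 genes of ribosomal proteins and 21 of 49 of mitochondrial oxidative phosphorylation were lower. In the platelet and megakaryocyte list 28 of 28 rose (28 adjusted over the list alone), with a median log2 change of 1.11. Thbs1 (probe set 1460302_at), which encodes the platelet granule protein thrombospondin, went from 7.54 ± 0.38 in controls to 9.91 ± 0.18, a log2 change of 2.37 ± 0.19 (SE, adjusted p = 9.19e-07). The largest rise among called genes outside the control range was that of Pde5a (probe set 1455970_at), a phosphodiesterase of cyclic GMP, at 2.58 ± 0.21 (SE, adjusted p = 9.19e-07), or 5.96-fold. Other rises among the largest were Mmp19, a matrix metalloproteinase (2.46 ± 0.23), and Ro60, an RNA-binding protein (2.20 ± 0.20). They also included Vwf, von Willebrand factor (2.14 ± 0.29), Slc6a4, the serotonin transporter (2.13 ± 0.18) and Vcl, the cytoskeletal protein vinculin (2.01 ± 0.18). Gp5, a subunit of the platelet receptor for von Willebrand factor, changed by 1.71 ± 0.18 (SE, adjusted p = 5.3e-06).

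Among ribosomal protein genes 30 of 40 fell (34 adjusted over the list alone), with a median of -0.66, including Rpl27a (-1.17 ± 0.22) and Rps18 (-0.91 ± 0.21). Of the oxidative phosphorylation genes, 21 of 49 fell (1 higher and 31 lower adjusted over the list alone), with a median of -0.42, including Ndufb5 of respiratory complex I (-0.94 ± 0.21). In the red cell and reticulocyte list 4 rose and 9 fell of 37 (4 and 13 adjusted over the list alone). Lower members included Prdx2, a peroxiredoxin abundant in red cells (-1.19 ± 0.13 SE, adjusted p = 9.66e-06), and Car2, a carbonic anhydrase (-1.01 ± 0.20). Gata1, Gata2, Nfe2 and Aqp1 rose. Gata1, Gata2 and Nfe2 encode transcription factors that act in megakaryocytes as well as in red cell precursors. Among called genes outside the control range, the largest falls were those of Hfe, a regulator of iron uptake (-1.51 ± 0.19 SE, adjusted p = 2.7e-05), and Atg4a, a protease of autophagy (-1.49 ± 0.21 SE, adjusted p = 8.42e-05). Blvrb, a biliverdin reductase of the oxidative-stress list, fell as well (-1.14 ± 0.16).

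Of the interferon-response genes 7 rose and 1 fell of 35 (9 and 1 adjusted over the list alone), led by Ifit3 (1.39 ± 0.22 SE, adjusted p = 3e-04) and Ifit2 (1.10 ± 0.19), with Irf7 the member that fell. Slfn4, a neutrophil-list gene that interferon also induces, rose by 1.75 ± 0.31. Of the p53 target genes 3 of 30 rose (4 adjusted over the list alone), namely Ccng1, cyclin G (0.88 ± 0.14 SE, adjusted p = 0.00042), Dglucy (0.55 ± 0.14) and Zmat3. After a repeated quantile normalization 11 interferon-response genes rose and 1 fell, and 6 p53 target genes rose and 1 fell. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, stood at 0.48 ± 0.16 (SE, adjusted p = 0.0562), short of the threshold. Few lymphocyte genes passed at this dose: in the B cell list 1 rose and 1 fell of 27 (1 and 1 adjusted over the list alone), Mef2c and Cd79a, and in the T cell list 2 of 26 fell (1 adjusted over the list alone), Cd3d and Cd3g. In the MHC class II and antigen presentation list 2 of 14 fell (3 adjusted over the list alone), H2-DMa and H2-Oa.

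The other lists at 0.5 Gy held few called genes. In the NK and cytotoxic cell list 1 of 21 fell (1 adjusted over the list alone), Ccl5. In the mature neutrophil list 1 rose and 1 fell of 27 (1 and 1 adjusted over the list alone), Slfn4 and G0s2. In the immature granulocyte list 1 rose and 1 fell of 18 (1 and 1 adjusted over the list alone), Syne1 and Chil3. Among monocyte genes 1 rose and 3 fell of 24 (1 and 3 adjusted over the list alone), F13a1 against Adgre4, Clec4a3 and Treml4. F13a1, the A chain of clotting factor XIII, is also a platelet transcript. Of the DNA repair genes 1 rose and 1 fell of 23 (0 adjusted over the list alone), Chek2 and Ddb2. Of the NF-kB and inflammatory genes 2 of 27 fell (2 adjusted over the list alone), Cd83 and Ier2. Oxidative-stress response genes moved both ways: 1 rose and 2 fell of 24 (1 and 2 adjusted over the list alone), Srxn1 against Blvrb and Gpx1. So did apoptosis regulators, of which 4 rose and 2 fell of 21 (4 and 4 adjusted over the list alone). By limma 0 of 16 changed (0 adjusted over the list alone) in the dendritic cell list. Likewise 0 of 22 changed (0 adjusted over the list alone) in the cell division list and 0 of 25 changed (0 adjusted over the list alone) in the DNA replication list. In these lists 1, 3 and 4 genes had an unadjusted p under 0.05, and the directional test of fry called none of these lists. Its mixed test, which ignores direction, passed for DNA replication (adjusted p = 0.0367). In all, limma called 1300 of 12696 genes at 0.5 Gy, 665 higher and 635 lower, of which 236 and 29 differed at least 2-fold. At any p, every 0.5 Gy array lay above all controls in 846 of the 12696 genes and below all of them in 576, where chance gives 0.794% of genes per direction.

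Camera called 9 of the 20 lists at 0.5 Gy. Platelets (adjusted p = 4.33e-36, and adjusted p = 0.0617 with an estimated correlation) and ribosomal proteins (adjusted p = 2.56e-19, and adjusted p = 0.404 with an estimated correlation) had the smallest p. It also called oxidative phosphorylation (adjusted p = 2.95e-11, and adjusted p = 0.47 with an estimated correlation), interferon-response genes (adjusted p = 0.000173, and adjusted p = 0.809 with an estimated correlation) and MHC class II (adjusted p = 0.000469, and adjusted p = 0.679 with an estimated correlation). The other called lists were p53 target genes (adjusted p = 0.0211, and adjusted p = 0.679 with an estimated correlation) and B cells (adjusted p = 0.022, and adjusted p = 0.826 with an estimated correlation), together with T cells (adjusted p = 0.022, and adjusted p = 0.826 with an estimated correlation) and red cells (adjusted p = 0.0496, and adjusted p = 0.826 with an estimated correlation). With an estimated correlation, 0 lists passed at any dose, and 2, 4 and 1 lists had an unadjusted p under 0.05 at 0.5, 1.0 and 3.0 Gy. Fry called 3, 6 and 14 lists. Per array, the mean level of the platelet list differed from control by 1.22 (exact p = 0.00794, adjusted p = 0.0298) in exact permutation tests. The difference was -0.55 (exact p = 0.00794, adjusted p = 0.0298) for MHC class II and 0.31 (exact p = 0.0159, adjusted p = 0.0454) for interferon-response genes. For ribosomal proteins it was -0.58 (exact p = 0.0238, adjusted p = 0.0621), for oxidative phosphorylation -0.39 (exact p = 0.0397, adjusted p = 0.0953) and for p53 target genes 0.14 (exact p = 0.0397, adjusted p = 0.0953), none of which passed after adjustment. Median and mean differed in sign for immature granulocytes, dendritic cells and the oxidative-stress list, none of them called. The arrays in which these lists moved were also those with 18S levels 2.17 above control.

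The count at 0.5 Gy fell to 810 genes without 0.5 Gy replicate 1 and to 765 without 0.5 Gy replicate 3. The 635 lower genes became 274 and 285 without these arrays, 374 without 0.5 Gy replicate 4, 400 and 335 without control replicate 1 or 4 and 928 without control replicate 2, so the even balance of directions rested on single arrays. The calls of Cd79a, Cd3d, Cd3g, Ccl5, Chil3, Chek2, Ddb2, Cd83, Srxn1, Gata1 and H2-Oa each ended without 0.5 Gy replicate 1 and also without replicate 3, with adjusted p between 0.0516 and 0.161. Those other than Cd83 and H2-Oa also ended without replicate 4. Without control replicate 1 the calls of Cd79a, Cd3g, Ccl5, Chil3, Chek2, Ddb2, Cd83, Srxn1 and Gata1 ended. Without control replicate 3 those of Cd79a, Cd3g, Chil3 and Ddb2 ended. Control replicate 4 was needed for Cd79a, Cd3g, Cd3d, Ccl5, Chil3, Chek2, Ddb2 and Cd83, and control replicate 2 for Chek2. The calls of Cd3g, Chil3, Chek2 and Ddb2 also ended without some arrays of the other doses, at adjusted p of 0.0603 or less. The calls of Adgre4, Ier2, Irf7, Mef2c, Syne1 and Zmat3 each ended without at least 1 array too (adjusted p up to 0.163). Among the lists, the call of p53 target genes ended without 0.5 Gy replicate 2 (adjusted p = 0.0563) and with a filter at the 75th percentile (0.0505). That of B cells ended without control replicate 1 or 4 or 0.5 Gy replicate 1 or 3 (up to 0.175). The T cell call ended without control replicate 1 or 4 or 0.5 Gy replicate 4 (up to 0.0965) and with that filter (0.0958). The red cell call ended without control replicate 1, 2 or 5, 0.5 Gy replicate 2, 1.0 Gy replicate 1, 2 or 3 or any 3.0 Gy array (up to 0.34). It also ended with that filter (0.144), the replicate number as a block (0.153), a repeated quantile normalization (0.0783), camera on ranks (0.0804) and either other choice of probe sets (0.0792 and 0.0915).

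With the 18S level in the fit, chosen after the data were seen, 557 genes passed at 0.5 Gy, and the calls of Car2, Gata1, Ifit2, Slfn4, Ccng1 and Dglucy were among those that ended. So did the list calls of p53 target genes, T cells and red cells. Over the 1300 genes the median absolute log2 change went from 0.69 to 0.99 and the median standard error from 0.16 to 0.33, so the median change did not shrink while the error grew.

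The second comparison set 1.0 Gy against control. Every gene of the platelet list rose, as at 0.5 Gy. Among interferon-response genes 25 of 35 rose, among p53 target genes 10 of 30 rose, and among red cell genes 14 of 37 fell. Of the platelet genes 28 of 28 rose (28 adjusted over the list alone), with a median of 1.57, including Thbs1 (2.88 ± 0.19 SE, adjusted p = 4.39e-08), Vwf (2.75 ± 0.29) and Nrgn, neurogranin (1.47 ± 0.13). Pde5a was again the largest rise among called genes outside the control range, at 3.15 ± 0.21 (SE, adjusted p = 4.39e-08), or 8.85-fold. Interferon-response genes: 25 rose and 1 fell of 35 (28 and 1 adjusted over the list alone), with a median of 0.77. Ifit3 went from 5.46 ± 0.09 to 8.10 ± 0.64 (2.64 ± 0.22 SE, adjusted p = 1.17e-07), Oasl1 changed by 1.95 ± 0.22, Ifit1 by 1.89 ± 0.23 and Slfn4 by 2.63 ± 0.31, while Irf7 fell.

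Of the p53 target genes 10 rose and 1 fell of 30 (10 and 1 adjusted over the list alone), with a median of 0.28. Ccng1 rose by 1.24 ± 0.14 (SE, adjusted p = 3.73e-06), Dglucy by 0.87 ± 0.14, Cdkn1a by 0.77 ± 0.16 (SE, adjusted p = 0.00156) and Phlda3 by 0.69 ± 0.14. Sesn1, a stress-induced sestrin, was the member that fell (-0.59 ± 0.16 SE, adjusted p = 0.0145), and that call ended without 1.0 Gy replicate 3, where its adjusted p was 0.0548. In the red cell and reticulocyte list 4 rose and 14 fell of 37 (4 and 19 adjusted over the list alone), with a median of -0.44. Epb42, protein 4.2 of the red cell membrane skeleton, changed by -1.78 ± 0.30 (SE, adjusted p = 0.00026), and Slc4a1, the anion exchanger of red cells, by -1.48 ± 0.23. Car2 changed by -1.73 ± 0.20 and Trim10 by -1.66 ± 0.20. Gata1, Gata2, Nfe2 and Aqp1 rose as at 0.5 Gy. Atg4a was the largest fall among called genes outside the control range, at -2.06 ± 0.21 (SE, adjusted p = 8.34e-07), or 4.17-fold lower. Txnrd2, a mitochondrial thioredoxin reductase (-1.77 ± 0.17), Hscb, a co-chaperone of iron-sulfur cluster assembly (-1.70 ± 0.15), and Fam210b (-1.69 ± 0.17) were also among the largest falls.

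Of the ribosomal protein genes 34 of 40 fell (35 adjusted over the list alone), with a median of -0.74. Of the oxidative phosphorylation genes 1 rose and 24 fell of 49 (1 and 28 adjusted over the list alone), with a median of -0.42 and Cox5a the member that rose. Rpl6 changed by -0.76 ± 0.19 and Atp5b, the beta subunit of ATP synthase, by -0.67 ± 0.11. In the T cell list 4 of 26 fell (6 adjusted over the list alone), namely Cd8b1 (-1.14 ± 0.26 SE, adjusted p = 0.00376), Cd3d (-1.11 ± 0.25), Cd3g (-0.93 ± 0.21) and Cd27. In the B cell list 1 rose and 1 fell of 27 (1 and 1 adjusted over the list alone), Mef2c and Cd79a (-0.87 ± 0.23), and in the MHC class II list 2 of 14 fell (8 adjusted over the list alone), H2-DMa and H2-Oa. For NK and cytotoxic cells 2 rose and 1 fell of 21 (2 and 1 adjusted over the list alone), Gzmb and Tbx21 against Klrd1. For mature neutrophils 2 rose and 3 fell of 27 (3 and 4 adjusted over the list alone), Slfn4 and Hdc against G0s2, Grina and S100a8. Immature granulocytes had a single call, Syne1: 1 of 18 rose (1 adjusted over the list alone). For monocytes 2 rose and 1 fell of 24 (2 and 1 adjusted over the list alone), F13a1 and Ms4a6d against Treml4. For dendritic cells 2 of 16 rose (1 adjusted over the list alone), Cd7 and Tcf4. For cell division 2 of 22 fell (2 adjusted over the list alone), Nusap1 and Ube2c. In the DNA replication list 1 gene rose, Dut, and 2 fell, Rfc5 and Rpa2, of 25 (0 adjusted over the list alone, where 9 genes had an unadjusted p under 0.05 in limma). For DNA repair 1 rose and 3 fell of 23 (1 and 3 adjusted over the list alone), Chek2 against Ddb2, Tdp1 and Xrcc6. For NF-kB and inflammatory genes 4 of 27 fell (3 adjusted over the list alone), Cd83, Ier2, Sod2 and Zfp36. For the oxidative-stress response 6 rose and 2 fell of 24 (7 and 4 adjusted over the list alone). For apoptosis regulators 4 rose and 5 fell of 21 (4 and 6 adjusted over the list alone). After a repeated quantile normalization 7 T cell genes, 5 B cell genes and 5 MHC class II genes were lower at 1.0 Gy, and 1 B cell gene was higher.

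Limma called 2195 genes at 1.0 Gy, 1117 higher and 1078 lower, of which 441 and 115 differed at least 2-fold. At any p, every 1.0 Gy array lay above all controls in 1001 of the 12696 genes and below all of them in 810. Camera called 8 lists. Platelets (adjusted p = 7.15e-35, and adjusted p = 0.0696 with an estimated correlation) and ribosomal proteins (adjusted p = 5.91e-18, and adjusted p = 0.236 with an estimated correlation) again had the smallest p. Interferon-response genes (adjusted p = 9.99e-18, and adjusted p = 0.188 with an estimated correlation) and oxidative phosphorylation (adjusted p = 2.99e-09, and adjusted p = 0.388 with an estimated correlation) followed. Further called lists were p53 target genes (adjusted p = 1.8e-05, and adjusted p = 0.188 with an estimated correlation) and red cells (adjusted p = 8.16e-05, and adjusted p = 0.388 with an estimated correlation). The last were MHC class II (adjusted p = 0.0032, and adjusted p = 0.687 with an estimated correlation) and T cells (adjusted p = 0.0114, and adjusted p = 0.84 with an estimated correlation). In exact permutation tests the mean level per array differed from control by 1.60 (exact p = 0.00794, adjusted p = 0.0298) for platelets, 0.93 (exact p = 0.00794, adjusted p = 0.0298) for interferon-response genes and 0.33 (exact p = 0.00794, adjusted p = 0.0298) for p53 target genes. It differed by -0.55 (exact p = 0.00794, adjusted p = 0.0298) for MHC class II, -0.70 (exact p = 0.0159, adjusted p = 0.0454) for ribosomal proteins and -0.43 (exact p = 0.0159, adjusted p = 0.0454) for red cells. Oxidative phosphorylation, at -0.43 (exact p = 0.0238, adjusted p = 0.0621), did not pass after adjustment. Median and mean differed in sign for monocytes, dendritic cells, cell division, the oxidative-stress list and apoptosis regulators, and in immature granulocytes both were below 0 while the test pointed up. The 18S level of these arrays was 2.76 above control.

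With the 18S level in the fit, 606 genes passed at 1.0 Gy, and the calls that ended included those of Ccng1, Dglucy, Cdkn1a, Phlda3, Sesn1, Cd8b1, Cd3d, Cd3g, Cd79a, Epb42, Slc4a1, Trim10, Rpl6, Atp5b, Slfn4, Gata1, Chek2, Hdc, Nusap1 and Ube2c. The list calls of p53 target genes, T cells and red cells ended too. The median absolute log2 change of the 2195 genes was 0.70 before and 0.96 after, and the median standard error 0.16 before and 0.39 after. The T cell list call ended without 1.0 Gy replicate 3 (adjusted p = 0.135). The calls of Klrd1, Treml4, Cd7 and Ddb2 ended without any of several single arrays, 1.0 Gy replicate 3 among them in each case (adjusted p = 0.062, 0.113, 0.127 and 0.0908). Those of Cd27, Cox5a, Dut, Grina, Gzmb, Ier2, Irf7, Mef2c, Ms4a6d, Rfc5, Rpa2, S100a8, Tbx21, Tcf4, Tdp1, Xrcc6 and Zfp36 each ended without at least 1 array (adjusted p up to 0.156).

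The third comparison set 3.0 Gy against control, at which the 18S level was 0.16 above control. Most B cell, T cell, MHC class II and ribosomal protein genes fell, and all platelet and most mature neutrophil genes rose. In the B cell list 24 of 27 fell (24 adjusted over the list alone), with a median log2 change of -2.81. H2-Ob, an MHC class II subunit of B cells (probe set 1440837_at), went from 8.64 ± 0.45 to 3.98 ± 1.04 (-4.66 ± 0.36 SE, adjusted p = 1.99e-08). Ighv14-2, an immunoglobulin heavy chain variable segment, changed by -5.10 ± 0.33 (SE, adjusted p = 5.92e-09), the largest change at this dose among called genes outside the control range. Bank1 changed by -3.77 ± 0.39, Fcmr, the receptor for immunoglobulin M, by -3.64 ± 0.30, Cd22 by -3.11 ± 0.29 and Cd79a by -2.56 ± 0.23. In the MHC class II list 13 of 14 fell (13 adjusted over the list alone), with a median of -2.21, including H2-Aa (-3.75 ± 0.34), H2-Ab1 (-3.72 ± 0.35), H2-Oa (-2.72 ± 0.23) and Cd74, the invariant chain (-3.05 ± 0.29). In the T cell list 21 of 26 fell (21 adjusted over the list alone), with a median of -1.05, including Cd8b1 (-3.36 ± 0.26 SE, adjusted p = 1.99e-08), Cd3g (-2.27 ± 0.21), Ccr7 (-2.47 ± 0.25) and Il7r (-2.10 ± 0.26). Btla, a receptor of B and T cells, changed by -3.73 ± 0.29.

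In the platelet list at 3.0 Gy 28 of 28 rose (28 adjusted over the list alone), with a median of 1.89, including Itgb5 (2.14 ± 0.16), Gp5 (2.22 ± 0.18) and Nrgn (1.85 ± 0.13). In the mature neutrophil list 20 rose and 1 fell of 27 (20 and 1 adjusted over the list alone), with a median of 0.94. Slfn4 rose by 3.58 ± 0.31 (SE, adjusted p = 4.92e-08), the histidine decarboxylase gene Hdc by 1.52 ± 0.18 and the lectin gene Clec4d by 1.48 ± 0.17, and Gda fell (-1.88 ± 0.27). In the immature granulocyte list 3 rose and 3 fell of 18 (2 and 3 adjusted over the list alone), Ceacam10, Lcn2 and Syne1 against Serpinb1a, Chil3 and Adpgk. In the monocyte list 3 rose and 10 fell of 24 (4 and 10 adjusted over the list alone), with Ccr2, a chemokine receptor of inflammatory monocytes, at -1.52 ± 0.19 and F13a1 at 1.69 ± 0.17. In the NK and cytotoxic list 1 rose and 3 fell of 21 (0 higher and 3 lower adjusted over the list alone), with Klrd1 at -1.44 ± 0.28 and Nkg7 at -0.67 ± 0.18. Ccl5 fell, and Serpinb9b rose in a call that ended without control replicate 1, 2 or 4 or 3.0 Gy replicate 2 or 4 (adjusted p up to 0.145). In the dendritic cell list 2 rose and 3 fell of 16 (2 and 3 adjusted over the list alone), with Irf8 (-2.40 ± 0.27) and Ly6d (-3.01 ± 0.33), which B cells also express, and Ccr9 lower, and Cd7 and Ccl22 higher. In the red cell list 7 rose and 21 fell of 37 (7 and 21 adjusted over the list alone), with a median of -0.51. Slc4a1 stood at -2.51 ± 0.23, Car2 at -2.41 ± 0.20 and Gata1 at 1.91 ± 0.17.

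The p53 target genes moved both ways at 3.0 Gy: 10 rose and 4 fell of 30 (10 and 4 adjusted over the list alone), with a median of 0.15. After a repeated quantile normalization 15 rose and 4 fell, with a median of 0.30, and after centring each array on its median 15 rose and 3 fell, with a median of 0.29. Camera did not call this list at 3.0 Gy (adjusted p = 0.104), while fry did (adjusted p = 0.0367). Its mean level differed from control by 0.08 (exact permutation p = 0.365). Limma called 49.1% of all genes tested at this dose, so a count of called genes near that share does not set a list apart. Phlda3 rose by 1.36 ± 0.14 (SE, adjusted p = 2.95e-07), Cdkn1a by 1.03 ± 0.16 (SE, adjusted p = 2.26e-05) and Ccng1 by 0.76 ± 0.14, while Sesn1 (-2.08 ± 0.16 SE, adjusted p = 2.06e-08), Btg2 (-0.85 ± 0.17), Rrm2b (-0.85 ± 0.18) and Apaf1 fell. Sesn1 and Btg2 restrain growth, Rrm2b supplies deoxynucleotides for repair, and Apaf1 assembles the apoptosome. Interferon-response genes: 17 rose and 3 fell of 35 (17 and 3 adjusted over the list alone), with a median of 0.38, against 23 and 2 after quantile normalization and 19 and 2 after centring. Ifit3 rose by 3.17 ± 0.22 (SE, adjusted p = 9.8e-09), or 9.03-fold, and Gbp3, Rsad2 and Tor3a fell. Tmem140 (2.99 ± 0.25), Fam110b (2.88 ± 0.22) and Frmd4b (2.83 ± 0.19) were also among the largest rises. Ribosomal proteins: 1 rose and 35 fell of 40 (1 and 35 adjusted over the list alone), with a median of -1.27, Rps18 at -2.52 ± 0.21, Rpl13a at -1.76 ± 0.15 and Rps16 the member that rose. Oxidative phosphorylation: 4 rose and 33 fell of 49 (4 and 34 adjusted over the list alone), with a median of -0.61 and Uqcrc2 at -1.47 ± 0.14; Cox5a, Cox6b1, Ndufa4 and Ndufs4 rose.

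Among DNA replication genes 4 rose and 12 fell of 25 (5 and 12 adjusted over the list alone), including the licensing factor Cdt1 (-2.18 ± 0.21 SE, adjusted p = 1.37e-07). The helicase subunit Mcm5 changed by -1.76 ± 0.22 and the polymerase clamp Pcna by -1.53 ± 0.17, while Dut, Cdc45, Pole and Rfc3 rose. In the DNA repair list 2 rose and 10 fell of 23 (2 and 10 adjusted over the list alone): the damage sensor Ddb2 changed by -1.42 ± 0.18 and the checkpoint kinase Chek2 by 0.83 ± 0.15. In the cell division list 8 rose and 3 fell of 22 (9 and 4 adjusted over the list alone), with Nusap1 at -2.07 ± 0.23, Ube2c at -1.38 ± 0.16 and Ccna2 at -0.80 ± 0.17, while Cdca8 rose by 0.71 ± 0.15. For NF-kB and inflammatory genes 7 rose and 12 fell of 27 (7 and 13 adjusted over the list alone), with Cd83, an activation marker of B and dendritic cells, at -2.57 ± 0.17 (SE, adjusted p = 7.38e-09). Lower too were Birc3, an inhibitor of apoptosis that acts in NF-kB signalling (-1.87 ± 0.19), and Tnfaip3, an inhibitor of that signalling (2.01-fold lower). For the oxidative-stress response 8 rose and 8 fell of 24 (8 and 8 adjusted over the list alone), with sulfiredoxin, Srxn1, at 2.12 ± 0.26 and Gpx1 at -0.87 ± 0.09. For apoptosis regulators 5 rose and 6 fell of 21 (5 and 6 adjusted over the list alone), with Birc2 at 1.67 ± 0.21 and Casp8 at -1.38 ± 0.19. The calls of Apaf1, Cdc45, Gbp3, Lcn2, Ndufa4, Rfc3, Rps16, Syne1 and Tor3a at 3.0 Gy each ended without at least 1 array (adjusted p up to 0.162). The balance of the apoptosis list and of the oxidative-stress list turned towards higher genes when each array was centred on its median (7 higher and 6 lower, and 11 higher and 6 lower). So did those of NK and cytotoxic cells (4 and 3) and immature granulocytes (9 and 3), while dendritic cells came to 3 and 3. Cell division came to 14 and 3 with this scaling and to 12 and 4 after quantile normalization, and DNA replication and DNA repair came to 6 and 10 and to 4 and 9 with it.

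Limma called 6237 genes at 3.0 Gy, 2534 higher and 3703 lower, of which 660 and 1407 differed at least 2-fold. At any p, every 3.0 Gy array lay above all controls in 1804 of the 12696 genes and below all of them in 2908. The balance of directions rested on the scaling: it was 3765 higher and 3254 lower after a repeated quantile normalization and 4494 higher and 3093 lower after centring each array on its median. These scalings moved the median gene by 0.102 and 0.139. With the second scaling the list medians were 2.03 for platelets, 1.08 for mature neutrophils and 0.51 for interferon-response genes. They were -2.67 for B cells, -2.07 for MHC class II, -0.91 for T cells, -1.13 for ribosomal proteins, -0.47 for oxidative phosphorylation and -0.38 for red cells. Camera called 9 lists at 3.0 Gy. Platelets (adjusted p = 3.73e-19, and adjusted p = 0.279 with an estimated correlation), ribosomal proteins (adjusted p = 1.04e-14, and adjusted p = 0.279 with an estimated correlation) and B cells (adjusted p = 4.5e-13, and adjusted p = 0.279 with an estimated correlation) had the smallest p. MHC class II (adjusted p = 1.21e-07, and adjusted p = 0.279 with an estimated correlation) and T cells (adjusted p = 5.35e-07, and adjusted p = 0.287 with an estimated correlation) came next. Oxidative phosphorylation (adjusted p = 6.35e-06, and adjusted p = 0.449 with an estimated correlation) and mature neutrophils (adjusted p = 4.66e-05, and adjusted p = 0.449 with an estimated correlation) were called too. So were interferon-response genes (adjusted p = 0.000108, and adjusted p = 0.496 with an estimated correlation) and red cells (adjusted p = 0.0119, and adjusted p = 0.522 with an estimated correlation), whose call ended with a filter at the 75th percentile (0.0645). In exact permutation tests the mean level per array differed from control by -2.44 (exact p = 0.00794, adjusted p = 0.0298) for B cells, -1.20 (exact p = 0.00794, adjusted p = 0.0298) for T cells and 0.83 (exact p = 0.00794, adjusted p = 0.0298) for mature neutrophils. It differed by 1.81 (exact p = 0.00794, adjusted p = 0.0298) for platelets, -1.25 (exact p = 0.00794, adjusted p = 0.0298) for ribosomal proteins and -0.56 (exact p = 0.0159, adjusted p = 0.0454) for red cells. In all, 12 of the 20 lists passed before and after adjustment. For dendritic cells the median was 0.00 and the mean -0.31, and for apoptosis regulators the median was 0.02 and the mean -0.05.

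**Figure D2:**
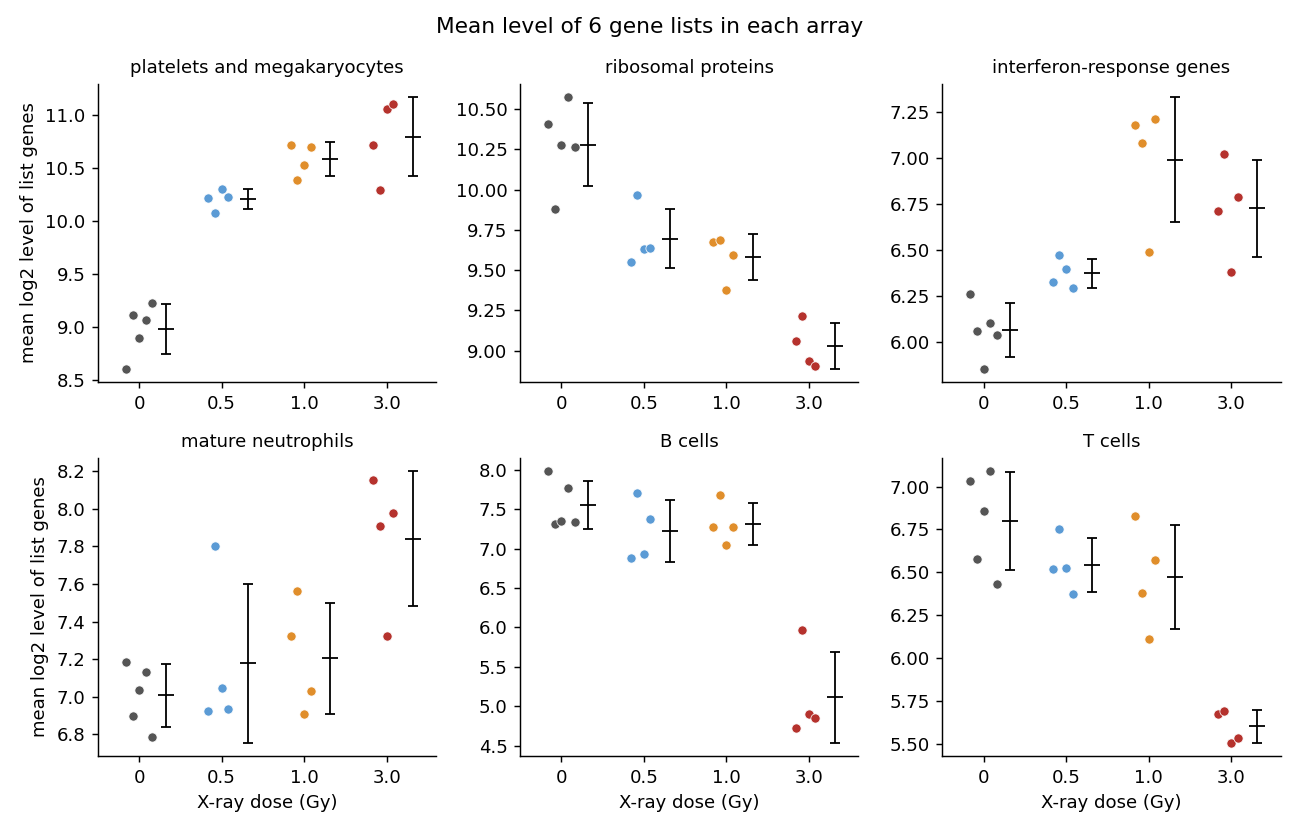
Mean log2 level of the genes of 6 lists (vertical axes) in each of the 17 arrays, by X-ray dose in Gy (horizontal axes, groups evenly spaced). Points are single mice and bars show the group mean and SD; the platelet list lies above every control at each dose, and the B cell and T cell lists drop below every control at 3.0 Gy.

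Comparisons between doses asked where the responses parted. Between 1.0 and 0.5 Gy limma called 2 genes, both lower at 1.0 Gy: Glrx5, a glutaredoxin of iron-sulfur cluster assembly (-0.92 ± 0.13 SE, adjusted p = 0.0129), and Hagh, a glyoxalase (-0.91 ± 0.14 SE, adjusted p = 0.0194), with 735 genes at an unadjusted p under 0.05. Adjusted over the list alone, 26 of 35 interferon-response genes were higher at 1.0 Gy, and 7 of 37 red cell genes, 3 of 22 cell division genes and 1 gene each of the NF-kB, oxidative phosphorylation and oxidative-stress lists were lower. This count was 0 without 0.5 Gy replicate 1, 3 or 4 and without 1.0 Gy replicate 1, 2 or 4. It was 9, 17, 42, 12 and 6 without control replicate 1, control replicate 3, 1.0 Gy replicate 3, 3.0 Gy replicate 2 and 3.0 Gy replicate 3. It was also 0 with the 18S level, with a robust intensity trend or with a 2-fold threshold. Other settings gave 1 with the mean of all probe sets, 9 with those groups alone, 8 over all probe sets, 21 after a repeated quantile normalization and 199 with array weights.

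Between 3.0 and 1.0 Gy, 4904 genes differed, 2016 higher and 2888 lower at 3.0 Gy. The 2016 became 1200 and 1215 without 1.0 Gy replicate 1 or 2. Ighv14-2 (-3.97 ± 0.34 SE, adjusted p = 1.86e-06) and Dock10, a guanine nucleotide exchange factor of lymphocytes (-3.00 ± 0.22), were lower at 3.0 Gy. So were Scd1, a fatty acid desaturase (-3.01 ± 0.27), Sfpq, a splicing factor (-2.91 ± 0.22), and Prpf4b, a kinase of the spliceosome (-2.49 ± 0.21). Ttc16 (1.31 ± 0.19) and the leukocyte gene Lst1 (1.03 ± 0.15 SE, adjusted p = 7.17e-05) were higher. Between 3.0 and 0.5 Gy, 4292 genes differed, 1633 higher (1049 without 0.5 Gy replicate 2) and 2659 lower, and Dock10 and Sfpq were again lower (-3.01 ± 0.22 and -2.86 ± 0.22). The B cell list mean lay 2.20 below its 1.0 Gy level and 2.11 below its 0.5 Gy level (exact permutation p = 0.0286 for both, the smallest that 4 against 4 arrays allow, adjusted p = 0.0903). At the same p the lists of T cells, MHC class II, ribosomal proteins, DNA replication, DNA repair and dendritic cells were lower than at both doses. Also at that p, the platelet and interferon lists were higher at 1.0 than at 0.5 Gy (0.38 and 0.62), oxidative phosphorylation was lower at 3.0 than at 1.0 Gy (-0.15), and red cells and apoptosis regulators were lower at 3.0 than at 0.5 Gy (-0.39 and -0.08). In these exact tests no list passed after adjustment. By gene, 15 of 28 platelet genes were called higher at 3.0 than at 0.5 Gy and 0 lower (19 higher adjusted over the list alone). Of 35 interferon-response genes 10 were lower at 3.0 than at 1.0 Gy and 0 higher (7 lower adjusted over the list alone), and 16 were higher and 1 lower than at 0.5 Gy. Camera called 7 lists between 1.0 and 0.5 Gy, 5 between 3.0 and 1.0 Gy and 7 between 3.0 and 0.5 Gy, and 0 with an estimated correlation. Fry called 1, 9 and 10: interferon-response genes between 1.0 and 0.5 Gy (adjusted p = 0.0336), and B cells among those between 3.0 and 1.0 Gy (adjusted p = 2.33e-05).

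The scalings turned the balance of these comparisons too. Between 3.0 and 1.0 Gy it became 3312 higher and 2438 lower after quantile normalization and 3862 higher and 2452 lower after centring, and between 3.0 and 0.5 Gy 2861 and 2376, and 3233 and 2252. With the 18S level in the fit, 0 genes differed between 3.0 and 1.0 Gy and 95 between 3.0 and 0.5 Gy. The median absolute log2 change of the called genes went from 0.61 to 0.51 and from 0.70 to 0.60, and the median standard error from 0.16 to 0.38 and from 0.17 to 0.33.

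A linear model asked which genes had a slope on the dose in Gy. Ttc16 rose by 0.63 ± 0.06 log2 units per Gy (SE) and Bcas3 by 0.53 ± 0.05. Trim59 changed by -0.93 ± 0.06 per Gy, Lmo2, a transcription factor of blood cell precursors, by -0.72 ± 0.04, Dapl1 by -0.80 ± 0.06, Cd83 by -0.84 ± 0.06 and Ighv14-2 by -1.72 ± 0.11. Cdkn1a rose by 0.31 ± 0.06 per Gy, and Car2 changed by -0.73 ± 0.10. The slope passed in 6020 genes, 2527 rising and 3493 falling, a balance that became 3821 and 3026 after quantile normalization and 4666 and 2881 after centring. A passing slope does not show that a gene followed the dose step by step. Sfpq passed (adjusted p = 0.000493 for the slope in limma), with changes from control of 0.96, 1.02 and -1.89 at 0.5, 1.0 and 3.0 Gy. The F test for a change at any dose passed in 6119 genes.

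**Figure D3:**
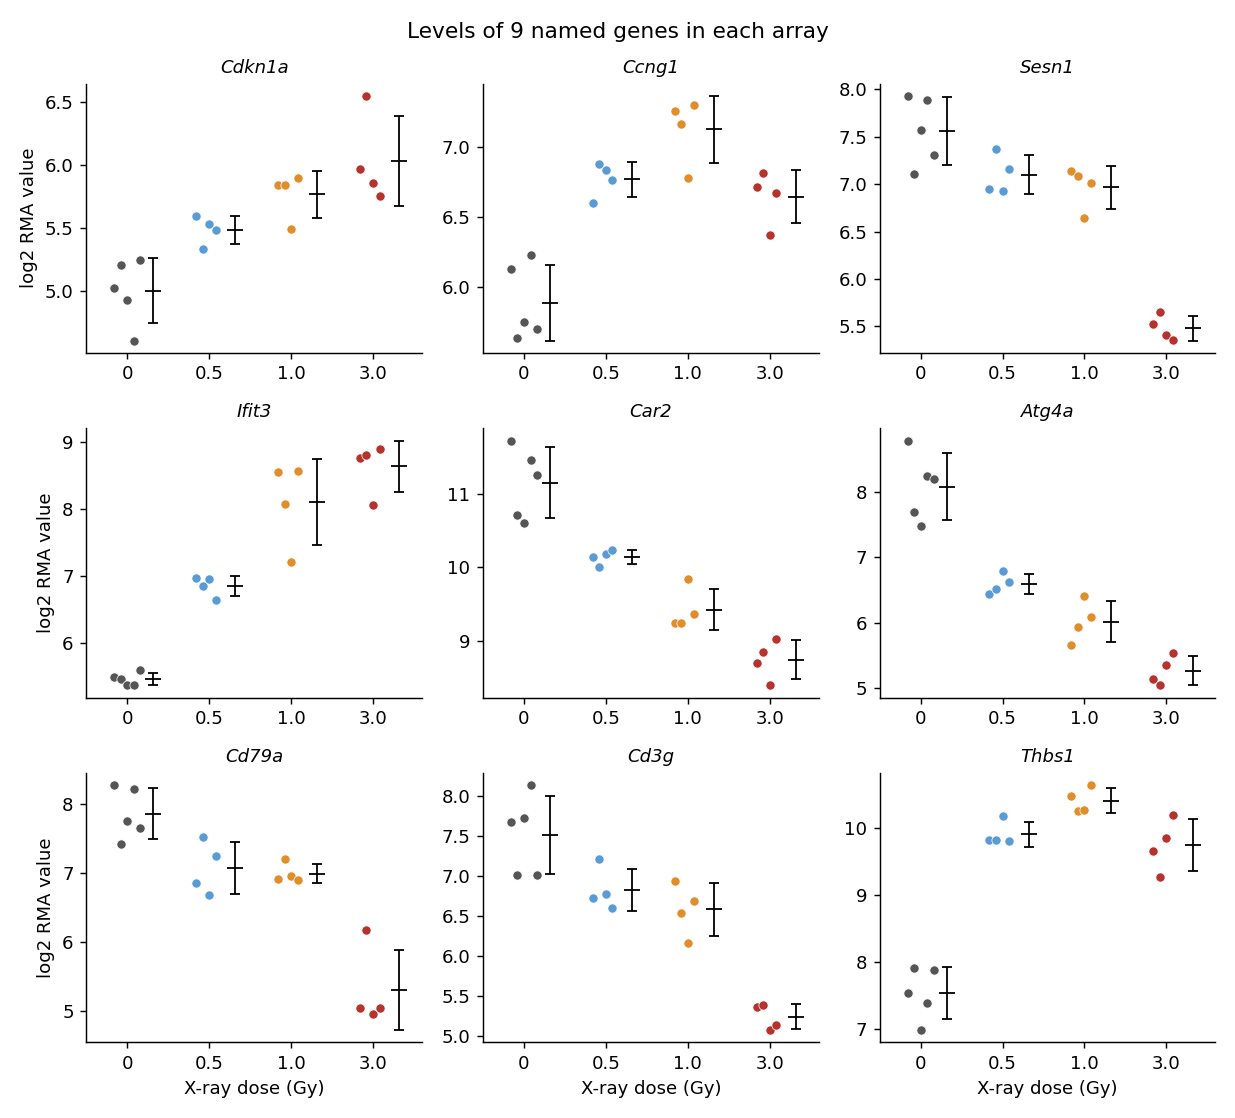
Log2 RMA level of 9 named genes (vertical axes) in each of the 17 arrays, by X-ray dose in Gy (horizontal axes, groups evenly spaced). Points are single mice and bars show the group mean and SD; Atg4a and Car2 step down with dose, Thbs1 is raised at every dose, and Cd79a, Cd3g and Sesn1 reach their lowest levels at 3.0 Gy.

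The responses at the 3 doses shared many genes. Genes called higher at both 0.5 and 1.0 Gy numbered 646 and genes called lower at both 531, where independent lists of these sizes would share 58.5 and 53.9. Between 0.5 and 3.0 Gy 619 and 563 were shared (132.7 and 185.2 for independent lists), and between 1.0 and 3.0 Gy 919 and 805 (222.9 and 314.4). Simulated unchanged groups against the same controls shared 0 calls. Nothing was changed in these groups, so few calls were likely and this 0 is no reference for the shared counts. Across genes, log2 changes at 0.5 and 1.0 Gy correlated at r = 0.912 against a simulated 0.455, with a covariance of 0.134 against a simulated 0.013. For 0.5 and 3.0 Gy r was 0.697 against 0.432 with a covariance of 0.176 against 0.012, and for 1.0 and 3.0 Gy r was 0.658 against 0.457 with a covariance of 0.211 against 0.013. The share of all genes with the same sign was 80.8% against a simulated 66.2% for 0.5 and 1.0 Gy and 69.5% against 65.1% for 0.5 and 3.0 Gy. For 1.0 and 3.0 Gy it was 63.1%, below the simulated 66.1%. With the controls split between the comparisons, over 10 splits, the mean covariances were 0.121, 0.163 and 0.199 and the median numbers of calls shared in the same direction 644.5, 749.5 and 1023.5. The arrays at 0.5 and 1.0 Gy also shared a higher level of the ribosomal RNA control probe sets, 2.17 and 2.76 above control. The simulations and the control splits cannot remove a processing difference common to these groups. How much of the agreement between 0.5 and 1.0 Gy is due to radiation therefore stays open. Called at all 3 doses were 606 genes higher and 484 lower at each, and 5 of mixed direction: Sfpq, Scd2 and Rps6ka3 were higher at the lower doses and lower at 3.0 Gy, and Cenpb and Ifi27l2b the reverse; calls of Cenpb, Ifi27l2b and Rps6ka3 ended without single arrays; with the mean of all its probe sets Sfpq was not called at 0.5 or 1.0 Gy (0.23 and 0.33). The remaining calls at 3.0 Gy included 4399 genes called at that dose alone, a count that does not test whether the lower doses differ from it.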

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

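The tests of the 18S level at 3.0 Gy against the platelet and interferon lists, both tests of radiation dose, the comparison of the platelet list with 4 other lists and all comparisons with the brighter genes of lists, those above their median level in controls, were chosen after the results they measure had been seen, as was the fit with the 18S level.

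The 18S ribosomal RNA control probe sets, which the comparisons of genes do not use, lay 2.17 log2 units above control at 0.5 Gy and 2.76 at 1.0 Gy. Among the 3921 kept probe sets with no single gene name, limma called 276 at 0.5 Gy, 464 at 1.0 Gy and 1519 at 3.0 Gy, which is 7.04%, 11.8% and 38.7% of them. These shares were below those of the kept probe sets with a single gene name, 9.81%, 17.2% and 48.2%.

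Single arrays stood far from the others of their group in 2 of 80 groups of list means and in 18 of 436 groups of genes whose values are printed, where chance gives about 1 in 20. The B cell list of 3.0 Gy replicate 2 stood at 5.97 against 4.73 to 4.91 in the other 3.0 Gy arrays, and the mature neutrophil list of 0.5 Gy replicate 2 at 7.80 against 6.92 to 7.05. For the named genes, the ranges are those of the other arrays in the group. Thbs1 stood at 10.19 in 0.5 Gy replicate 3 against 9.81 to 9.83. Ro60 stood at 6.43 in 0.5 Gy replicate 2 against 6.69 to 6.74. Blvrb stood at 8.67 in 0.5 Gy replicate 2 against 9.02 to 9.02. Ifit3 stood at 8.06 in 3.0 Gy replicate 3 against 8.77 to 8.90. Ifit2 stood at 5.84 in control replicate 1 against 6.14 to 6.24. Slfn4 stood at 5.96 in control replicate 2 against 6.9 to 7.28. Dglucy stood at 6.09 in 3.0 Gy replicate 2 against 5.53 to 5.62. Cdkn1a stood at 5.49 in 1.0 Gy replicate 3 against 5.84 to 5.90. Nrgn stood at 10.53 in control replicate 1 against 10.9 to 11.05. Slc4a1 stood at 8.86 in 1.0 Gy replicate 1 against 9.53 to 9.67. Cd79a stood at 6.18 in 3.0 Gy replicate 2 against 4.96 to 5.05. Fcmr stood at 6.97 in 3.0 Gy replicate 2 against 5.24 to 5.46. H2-Oa stood at 6.71 in 3.0 Gy replicate 2 against 5.54 to 5.61. Glrx5 stood at 10.27 in 1.0 Gy replicate 3 against 10 to 10.04. Ttc16 stood at 4.73 in 0.5 Gy replicate 3 against 4.27 to 4.34. Lst1 stood at 7.61 in 1.0 Gy replicate 1 against 7.84 to 7.87. Lmo2 stood at 7.72 in 1.0 Gy replicate 1 against 7.89 to 7.92. Chil3 stood at 7.53 in 0.5 Gy replicate 2 against 5.71 to 6.00.

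Regrouping the arrays tested whether chance could give as many calls. At 0.5 Gy 2 of 100 splits gave as many genes as the real 1300, the real one included, and the highest other count, 1351, came from a split that put control replicate 2 with the 0.5 Gy arrays against the other controls, close to the mirror of the real one. For 1.0 Gy, 3.0 Gy, the linear trend and a change at any dose 1 of 100 splits, the real one, gave the real count (2195, 6237, 6020 and 6119), and the highest others were 1786, 5333, 1502 and 975. Between doses 1 of 35 splits gave 2 genes for 1.0 against 0.5 Gy (highest other 1), 4904 for 3.0 against 1.0 Gy (highest other 2782) and 4292 for 3.0 against 0.5 Gy (highest other 41). Chance is thus an unlikely source of these counts of genes, but ranks among 100 or 35 splits cannot exclude it. The 2 genes between 1.0 and 0.5 Gy are an exception. Their count stood 1 above the highest other split and became 0 without any of 6 single arrays. Chance stays open for the counts of lists. As many as the real 9, 8 and 9 lists at 0.5, 1.0 and 3.0 Gy came from 9, 32 and 27 of 100 splits. Other splits gave up to 13, 12 and 13.

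Platelet genes were higher at every dose. A processing difference marked by 18S is argued against at 3.0 Gy, where 18S stood at the control level and the list mean was 1.81 higher (exact permutation p = 0.00794). At 0.5 Gy the rise was 1.22 ± 0.16 (SE) before and 1.39 ± 0.35 with 18S in the fit. That fit adjusts only for 18S differences within groups, so it cannot decide on a processing difference between the groups. A loss of other cells that raised all remaining types alike is argued against at 0.5 Gy, where the list rose by 1.25 above the mean of the NK, neutrophil, monocyte and dendritic lists (exact permutation p = 0.00794) and by 1.29 above their brighter genes (exact permutation p = 0.00794). These comparisons do not cover a loss that took in those cell types as well, which stays open. Whether the rise follows the radiation dose stays open: the list mean differed by 0.588 between 3.0 and 0.5 Gy (exact permutation p = 0.0571), while 15 of 28 genes were called higher and 0 lower and fry gave an adjusted p of 0.0104. Part or all of the low-dose rise may go with 18S, since 18S nearly follows the groups.

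Ribosomal protein genes were lower at every dose. At 0.5 Gy their list fell further than the NK, neutrophil, monocyte and dendritic lists by a difference of -0.558 (exact permutation p = 0.0159). Against the brighter of those genes it was -0.518, and -0.370 with neutrophils left out (exact permutation p = 0.0159 and 0.0476). These brighter genes lay at 7.71 and 7.20 in controls, below the 10.28 of the ribosomal list, so they may understate a dilution. The ribosomal list thus fell further than these genes, but dilution by platelet RNA stays open. The ribosomal fall at 0.5 Gy went beyond the B and T cell lists by -0.291 (exact permutation p = 0.0397), but a loss of these cells stays open. Their dimmer genes fell less at 3.0 Gy (-1.22 against -2.46 in the brighter ones), so list means may understate it. Beyond the brighter ones the difference at 0.5 Gy was -0.202 (exact permutation p = 0.143). At 3.0 Gy the ribosomal list mean changed by -1.25, against -2.44 for B cells and -1.20 for T cells. The 18S level was 2.17 above control at 0.5 Gy, so a processing difference stays open at that dose. Fewer reticulocytes may contribute and stay open. The smallest change of the red cell list over the 3 doses was -0.174, at 0.5 Gy (exact permutation p = 0.175). At 1.0 and 3.0 Gy it was -0.430 and -0.565 (exact permutation p = 0.0159 for each). The list holds Gata1, Gata2 and Nfe2, which also act in megakaryocytes and rose at the lower doses, so its mean may understate a fall.

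Interferon-response genes had their highest list mean at 1.0 Gy. More monocytes as the whole cause are argued against by a rise of 0.75 above the monocyte list at 1.0 Gy (exact permutation p = 0.00794). The monocyte list itself differed from control by 0.177 at 1.0 Gy (exact permutation p = 0.389), and no comparison with its brighter genes was made. A contribution of monocytes therefore stays open. A processing difference marked by 18S is argued against at 3.0 Gy, where the list mean was 0.662 higher with 18S at the control level (exact permutation p = 0.00794). Whether the response depends on the radiation dose beyond 1.0 Gy stays open, at a difference of -0.264 between 3.0 and 1.0 Gy (exact permutation p = 0.286), with 10 of 35 genes called lower, 0 higher and an adjusted p of 0.228 from fry, and at the lower doses 18S could contribute.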

How the results depend on the processing

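The fit with the 18S level was chosen after the data were seen. Total counts of genes kept their size, within 1.5 times, under the alternatives not listed here. The numbers higher or lower could move further: at 3.0 Gy the 2534 higher genes became 4494 after centring. With array weights 2437 genes passed at 0.5 Gy and 199 between 1.0 and 0.5 Gy. Over all probe sets, where more features were tested, 2282, 3988 and 11377 passed at 0.5, 1.0 and 3.0 Gy, 8, 8977 and 7819 for 1.0 against 0.5, 3.0 against 1.0 and 3.0 against 0.5 Gy, 11029 for the trend and 11246 at any dose. A 2-fold threshold, stricter by construction, left 265, 556, 2067, 0, 1018 and 1045. With the 18S level 557, 606, 0, 0 and 95 passed at 0.5 and 1.0 Gy and between 1.0 and 0.5, 3.0 and 1.0, and 3.0 and 0.5 Gy. Between 1.0 and 0.5 Gy the count was also 1 with the mean of all probe sets, 21 after quantile normalization, 0 with a robust intensity trend and 9 with those groups alone. An estimated correlation left 0 lists at 0.5, 1.0 and 3.0 Gy, and fry 3 at 0.5 and 14 at 3.0 Gy. Leaving out single arrays gave 765 to 1622 genes at 0.5 Gy, 1704 to 2344 at 1.0 Gy and 5400 to 6403 at 3.0 Gy. It gave 0 to 42 between 1.0 and 0.5 Gy, 3566 to 5759 between 3.0 and 1.0 Gy and 3083 to 4487 between 3.0 and 0.5 Gy. For the trend it gave 4981 to 6219, at any dose 5282 to 6776, and 6 to 10, 7 to 10 and 9 to 10 lists. Of 60 list means, 21 to 27 had an exact permutation p under 0.05 before adjustment, against 25 in the full data. Of 94, 124 and 176 calls at the 3 doses of genes named by the rule or outside it, 30, 33 and 15 ended without at least 1 array, and 55, 71 and 1 ended with the 18S level. With it Scd2 reversed to -0.121 at 0.5 Gy and -0.107 at 1.0 Gy, and Treml4 and Ms4a6d to 0.277 and -0.055 at 1.0 Gy. Tor3a at 3.0 Gy reversed to 0.088 with a probe set other than _x_at and _s_at. Other settings ended calls of named genes too. With the mean of all probe sets 9 of 94, 10 of 121 and 4 of 172 ended at the 3 doses, and after quantile normalization 1, 4 and 3. Replicate numbers gave no clear pairing of the arrays. Residuals of same-numbered arrays correlated at a median r of 0.067 (-0.454 to 0.495) and those of different-numbered arrays at -0.0255. Of 16 arrays, 7 correlated best with an array of their own number. With replicate numbers as a block 1208, 2032 and 6341 genes passed at the 3 doses, and 6, 11 and 5 of the calls of named genes ended. Beyond the features tested and the stricter threshold, the cause was not tested. Signal over background cannot be read from the deposited values.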

Other observations

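All tests in this part were chosen after the data were seen.

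Of the 646 genes called higher and 531 called lower at both 0.5 and 1.0 Gy, 606 and 484 were called the same way at 3.0 Gy, against the same controls. A minority of 24 and 13 differed at 3.0 Gy from both lower doses in the direction of control, for which no count by chance was made. They included the heat shock proteins Hsph1 (1.53 ± 0.23 at 1.0 Gy and 0.73 ± 0.23 at 3.0 Gy, log2 change and SE) and Hsp90aa1 (1.08 ± 0.15 and -0.21 ± 0.15 at these doses), the cyclin gene Ccnd2 (1.28 ± 0.25 and -0.32 ± 0.25) and Jak1, a kinase of cytokine receptors (0.91 ± 0.20 and 0.24 ± 0.20). The counts of 24 and 13 take in 3 and 2 genes that went past control and were called in the opposite direction at 3.0 Gy. The arrays at 0.5 and 1.0 Gy are also those with the higher 18S level.

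In 7 rising and 15 falling genes the arrays of the 4 groups followed the dose without overlap, among them Rap2a, a small GTPase (1.36, 1.66 and 2.26 log2 units above control at the 3 doses), Eif5, a translation initiation factor (-0.86, -1.25 and -2.20) and Acp1, a phosphatase (-0.99, -1.42 and -2.27). With 0.5 and 1.0 Gy as a single level 41 genes rose and 41 fell without overlap. No count by chance was made for either order.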
